A study of Homo sapiens with 384 samples.

How the data were processed

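Nuclei of cardiomyocytes differentiated from WTC11, an established line of human induced pluripotent stem cells, were profiled by single-cell combinatorial indexing RNA sequencing (sci-RNA-seq) with 2 levels of indexing. The cells carried tetracycline-inducible short hairpin RNAs (shRNAs) against GATA4, NKX2-5, SMAD2, KMT2D or CHD7, or a scrambled hairpin, in the AAVS1 locus, a site often used to hold transgenes. The labels name the wells of a plate, all harvested on day 23, while the series text names 2 batches, harvested on days 21 and 25. Nuclei were released by hypotonic lysis and fixed with paraformaldehyde, so cytoplasmic RNA was not measured.

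The authors' notes name bcl2fastq 2.20.0.422, Trim Galore 0.6.10, STAR 2.5.1b, SAMtools 1.7 and bedtools 2.27.1, and name the builds GRCh38, hg19 and mm10 without saying which step used which. How cells and genes were filtered is not stated. The authors deposited a table of whole-number counts per gene and nucleus, whose column sums equal the total count in the cell table for all 3364 nuclei. A further table deposited by the authors holds log10 values. On its first 300 genes these equalled the log10 of the count divided by the nucleus's size factor plus 1, within 1e-09. This table was used for no result. In the deposited cell table the mitochondrial and ribosomal shares are in percent of a nucleus's counts. The size factor deposited by the authors is a ratio, proportional to the total count. The hairpin, the clonal identifier, the cell class, a batch code and a condition code were taken from the authors' cell table as given. The meaning of the condition codes 1N and 2N and of the batch codes n3 and n4 is not stated. Another 28 columns of the cell table were not used.

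Raw counts were summed per clone, defined as a hairpin with a clonal identifier. The clone was the replicate, and nuclei and wells were never treated as replicates. Of 37 clones, 19 had at least 10 nuclei and entered the tests, and the 18 smaller clones were left out of them. Genes were kept by filterByExpr, scaled by the trimmed mean of M values (TMM) and tested with the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3, two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. All targets shared a single fit with the batch code as a covariate. In that fit, which also gave n3 against n4, each gene's spread was taken fully from the trend over genes of like abundance. A gene's own spread between clones therefore did not enter its SE or p-value. Each target was compared with the scrambled clone, and, as an alternative, with all other clones. The scrambled arm had a single clone, which was assumed to vary like the others. GATA4 clone CTTCGG is the only tested clone labelled with both batches. With the batch covariate it therefore carries no information on the target differences themselves. Fixed gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, all from limma 3.58.1. A list needed at least 5 tested genes. Shares of nuclei per class were compared between clones by exact permutation tests, and between condition codes within clones by exact sign-flip tests.

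The batch and condition codes were planned as values only, as CPM (counts per total of 1000000) over pooled nuclei, because each code may hold a single preparation. The edgeR tests of n3 against n4, with the target as covariate, and of 1N against 2N, with the clone as a block, were added after the data were examined. Their p-values measure whether clones share a difference, and they do not measure the spread between preparations. Each of the 96 reverse transcription wells holds nuclei of a single condition code, 48 wells for each, so the code and those wells cannot be separated.

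Hairpin target sequences were matched to the transcripts of GENCODE release 29 on GRCh38, and coordinates count from 1. Of the 15079 genes, 15045 had a location in that annotation. Gene span is the distance from a gene's start to its end there.

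Genes are named by a rule set before the data were examined. It takes the targeted gene, the 10 genes with the smallest p in each direction among those past the threshold, and 2 to 4 members of each described list with the smallest p. Where nothing was tested it takes the 10 highest and the 10 lowest CPM ratios among genes with at least 50 counts. For classes it takes the 10 leading genes by fold among genes seen in at least 10% of the nuclei. Genes of the sex chromosomes are not named. Some genes that the rule takes, for the CM3 class and for the CPM ratios of the condition codes, are not reported here. The 15 gene lists and the cell-type markers were fixed before the data were examined.

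Each fit was tested on simulated counts for the real genes with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those at or above the median abundance, and all clones were simulated from the same mean profile. The shares that follow therefore do not cover genes with lower counts. Against the single scrambled clone, 0% to 5% of the 2-fold changes and 13% to 49% of the 4-fold changes were called over the 5 targets, on 8881 genes. Against all other clones these shares were 12% to 69% and 71% to 100%. For n3 against n4 they were 53% and 99%, and for 1N against 2N, on 3730 genes, 99% and 100%. At most 9 of 8681 unchanged genes were called in any of these.

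Intervals are 95% intervals. Those of CPM values are exact Poisson intervals and cover counting error only, as does the limit for a count of 0, set at 3 counts. Those of slopes, the part of a log2 change that called genes kept in another fit, resample genes and do not measure the spread between clones. Alternatives covered DESeq2 1.42.0, library size without TMM factors, no gene filter, clones with at least 5 or at least 20 nuclei, the control arm of all other clones, nuclei outside the CF class, no batch covariate, and clones left out in turn. Against the scrambled clone these were the clones of each target but GATA4, and against all other clones those of each target. For n3 against n4 only n3 clones were left out, and for 1N against 2N none. For CPM ratios they covered nuclei with at least 500 counts and CPM without mitochondrial genes and the 20 most counted genes. Fits on a single condition code, a single batch code or the CM2 class were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.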

Results

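The series asked how hairpins against the cardiac transcription factors GATA4 and NKX2-5, the TGF-beta signal transducer SMAD2, the histone methyltransferase KMT2D and the chromatin remodeler CHD7 change cardiomyocytes that differentiate as a mixed pool. Each nucleus carried a hairpin barcode and a clonal identifier that marks the descendants of an edited cell. The deposited data held 3364 nuclei with 15079 genes and 7210120 counts. The median nucleus had 1761 counts, with a range of 423 to 13624, and 889 detected genes, with at most 4350. Nuclei lay in all wells but 1, with a median of 9 nuclei per well, a range of 1 to 18, and a median of 17684 counts per well, a range of 712 to 61285. GATA4 hairpins were in 36.7% of the nuclei (12 clones), SMAD2 hairpins in 26.96% (5 clones), NKX2-5 hairpins in 19.1% (7 clones), KMT2D hairpins in 10.5% (7 clones) and CHD7 hairpins in 3.24% (4 clones). The scrambled hairpin was in 3.54% of the nuclei (2 clones). Clones with at least 10 nuclei numbered 7 for GATA4, 3 each for SMAD2, NKX2-5 and KMT2D, 2 for CHD7 and 1 for the scrambled hairpin, which is coded n4. The largest 4 clones held 66.8% of all nuclei.

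The 12 targeting hairpins matched their intended genes on GRCh38, and 0 other genes matched. GATA4.1 matched chromosome 8, 11759549 to 11759570, in the 3' UTR in exon 7, and GATA4.3 matched 11757010 to 11757031 in coding exon 6. NKX2.5.2 matched chromosome 5, 173232663 to 173232683, in the coding part of exon 2, and NKX2.5.3 matched 173232367 to 173232388 in the 3' UTR of the same exon. SMAD2.2, SMAD2.3 and SMAD2.4 matched coding sequence on chromosome 18, at 47896568 to 47896588 in exon 2, 47845731 to 47845752 in exon 9 and 47841828 to 47841848 in exon 11. KMT2D.1, KMT2D.2 and KMT2D.3 matched coding sequence on chromosome 12, at 49052148 to 49052168 in exon 10, 49027017 to 49027037 in exon 48 and 49046281 to 49046301 in exon 16. CHD7.1 matched chromosome 8, 60822057 to 60822077, in coding exon 11, and CHD7.4 matched 60866109 to 60866129 in the 3' UTR in exon 38. The scrambled hairpin matched no transcript.

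The authors placed the nuclei in 5 classes, whose leading genes describe them and are not a test. Early cardiomyocytes (CM1, 736 nuclei, 21.9%) were led by NPPB at 5.08-fold its level in all other nuclei, ANKRD1, ATF3, TUBB2B, ACTA1, IRS2, CCN2, GADD45A, ADAMTS15 and CREB3L1. Mid cardiomyocytes (CM2, 1210 nuclei, 35.97%) were led by TCAP at 2.29-fold, ALDOC, PYGM, CRYAB, NDUFC1, MYL2, FHL2, CKM, FABP3 and RRAD. Late cardiomyocytes (CM3, 937 nuclei, 27.9%) had among their leading genes RGS6 at 4.04-fold, SPHKAP, KCNH7, DLG2, ADAMTS19, ERBB4, TBX20, CACNA1D and CNTN5. Proliferative cardiomyocytes (P-CM, 8.89%) were led by the mitotic genes PBK at 54.2-fold, CEP55, DEPDC1, KIF14, KIF20A, PLK1, KIF18B, CDC6, NDC80 and BIRC5. Cardiac fibroblasts (CF, 5.41%) were led by SULF1 at 774-fold, MGP, LUM, PTX3, COL6A3, ACTG2, TNC, SUCNR1, TGFBI and PTGIS. Median counts per nucleus were 2588 in CM1, 1167 in CM2, 1819 in CM3, 2425 in P-CM and 2664 in CF. Over all nuclei, 12 cardiomyocyte markers summed to 87290 CPM, of which TTN gave 48274. Fibroblast markers summed to 2512 CPM, of which COL1A1 gave 862.7, and smooth muscle markers to 6899.6, of which TAGLN gave 4396.7. Neural markers summed to 2799.5 CPM, of which NES gave 2281.4, and skeletal muscle markers to 2564, of which ACTA1 gave 2542.4. A sum carried by a single gene does not show that nuclei of that type were present. Cycling markers summed to 541.3 CPM, epicardial markers, mostly KRT19, to 287.8 and cardiac progenitor markers to 137.03. Endothelial markers summed to 70.9 CPM, pluripotency markers to 30.2, endoderm markers to 28.6 and blood markers to 12.2.

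Condition codes 1N (1878 nuclei, median 1632 counts) and 2N (1486 nuclei, median 1969 counts) were both present in most clones, which allowed a comparison within 12 clones over 3730 genes. In this edgeR test 632 genes passed the threshold, 53.2% of them higher and 46.8% lower in 1N nuclei, and 1166 had an unadjusted p under 0.05. With library size alone the balance turned, with 45.6% of the called genes higher and 54.4% lower. IGFBP5 was higher by 1.86 ± 0.15 on the log2 scale (SE), with a mean of 396 CPM in 1N and 97.4 CPM in 2N nuclei. SPHKAP was higher by 2.19 ± 0.19, the neuregulin receptor ERBB4 by 1.17 ± 0.10 and the sarcomere gene TTN by 0.53 ± 0.05. KCNQ5, NREP, TECRL, LAMA2, PDGFD and PLCXD3 were the next by p and rose by 1.18 to 1.45. Each of these 10 genes was higher in 12 of 12 clones. The keratin genes KRT18 and KRT8 changed by -1.30 ± 0.14 and -1.01 ± 0.11, with means of 439 and 1321 CPM in 1N against 1146 and 2693 CPM in 2N nuclei. PHGDH (-1.26), S100A10 (-1.24), SLC1A5 (-1.42), CRABP2 (-0.86), ETV5 (-1.81), SYNPO (-1.13), YARS1 (-0.80) and the cell-cycle inhibitor CDKN1A (-1.17) were also lower in 1N nuclei. Within the CM2 class alone, over 9 clones and 972 genes, IGFBP5 (1.95), TTN (0.45), LAMA2 (0.91), YARS1 (-1.13) and CRABP2 (-0.64) passed the threshold again. There SPHKAP had 0.90, NREP 0.71, KCNQ5 0.62, PDGFD 0.56, TECRL 0.41, ERBB4 0.27, KRT8 0.05, KRT18 -0.11, S100A10 -0.21, CDKN1A -0.63 and PHGDH -0.64, none past it, and PLCXD3, SLC1A5, ETV5 and SYNPO were not tested. The risen genes were long, with a median span of 222.1 kb, and the fallen ones short, with a median of 16.5 kb. Across all tested genes the log2 change and the span had a Spearman rho of 0.529, and genes are not independent replicates.

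**Figure D1:**
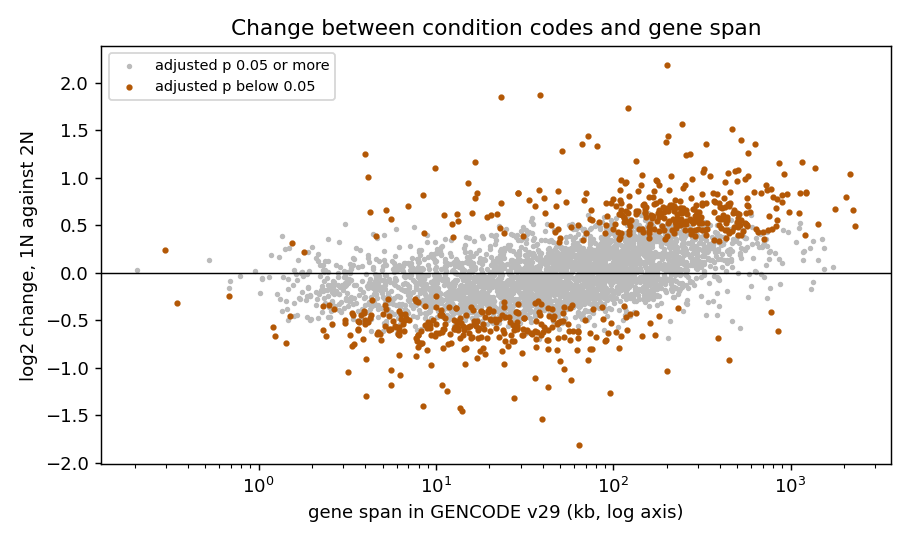
Log2 change between nuclei coded 1N and 2N, within 12 clones, against gene span in kb on a log axis, with a point per tested gene and the genes past the threshold in orange. Among the 632 genes past the threshold, risen ones had a median span of 222.1 kb and fallen ones 16.5 kb.

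Among the fixed lists, calcium handling and excitation rose most broadly in 1N nuclei, with 12 of 14 genes past the threshold, among them CACNA1C (0.93), RYR2 (0.80), TRDN (0.79) and SLC8A1 (0.62). Within the CM2 class alone these had 0.54, 0.07, -0.05 and 0.34, none past the threshold. Its camera adjusted p was 6.32e-12, and 0.000507 with an estimated correlation. The list tests took no account of gene span, which had a Spearman rho of 0.529 with the log2 change. How much of the list results follows span was not tested. The ventricular list also rose by camera, with an adjusted p of 0.0384 with an estimated correlation, through FHL2 (1.34), MYL2 (1.10), PRDM16 (0.76) and MYH7 (0.47), while MYL3 (-0.31), named after its value was seen, was lower and 1 of its 6 genes did not pass. Another 3 camera calls were lost with an estimated correlation. Fry called these 3 lists, sarcomere up (adjusted p 0.000579), p53 down (0.000295) and TGF-beta down (0.00374). The sarcomere list had adjusted p = 0.0800 with an estimated correlation, with 9 of 26 genes higher and 4 lower, among them MYOM1 (0.58) and ANKRD1 (-0.54), which had 0.47 and 0.42 within the CM2 class, neither past the threshold. The p53 list, in which CDKN1A and PHLDA3 (-0.65, and -0.60 but not past the threshold in the CM2 class) were lower, had adjusted p = 0.0548 with an estimated correlation. The TGF-beta list, with 6 of 15 genes lower and LTBP1 (0.42, named after its value was seen) higher, among them CCN2 (-1.04), ID1 (-0.67), BAMBI (-0.59) and TAGLN (-0.45), had adjusted p = 0.206 with an estimated correlation. TAGLN turned to 0.54 within the CM2 class, past the threshold, and had -0.16 in n3 clones alone, while CCN2 had -0.35 and ID1 -0.62 in n4 clones alone, none of these past it. Lists not called by camera still held changed genes, such as TBX20 (1.28), HAND2 (0.67) and MEF2A (0.64) of the cardiac transcription factors, HDAC9 (1.04) and KMT2C (0.46) of the chromatin regulators, VCAN (0.67) and FN1 (-0.80) of the extracellular matrix, CKM (0.79) and CS (-0.41) of oxidative metabolism, HSPB7 (0.57) of the heat-shock list, PAM (0.44) of the atrial list and TPX2 (-0.81) of the proliferation list. Of these, KMT2C (0.14), HAND2 (0.27), MEF2A (0.24), HDAC9 (0.46), VCAN (0.25), PAM (0.39) and HSPB7 (0.36) did not pass within the CM2 class, VCAN (-0.11) and TPX2 (-0.50) in n3 clones alone, or TBX20 (0.60), HAND2 (0.25), KMT2C (0.59) and FN1 (-0.72) in n4 clones alone. The interferon, WNT and glycolysis lists were not called by camera either. Of the lists that camera did not call, fry called the cardiac transcription factors (adjusted p 0.00445), chromatin regulators (0.0139) and oxidative metabolism (0.0140), each up.

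Pooled CPM, the planned form for these codes, differed 2-fold or more for 416 of 10504 genes with at least 50 counts, 51.9% of them higher in 1N nuclei. NLRC3, LAT2, DSCAML1, SLC9B1, LINGO1, MARCHF11, HEY2, FGF12 and CDH13 were among the genes with the highest ratios. TPPP3, MCTP1, SST, CALB2, GDF15, HEYL, C3orf70, CHAC1, THBS3 and NGFR had the lowest ratios. Fibroblasts were 3.51% of 1N and 7.81% of 2N nuclei, lower in 9 of 12 clones, with an exact sign-flip adjusted p of 0.0452. P-CM nuclei were 7.29% of 1N and 10.9% of 2N nuclei in the pool, and 6.66% and 11.5% as means over clones. They were lower in 10 of 12 clones, with an adjusted p of 0.0415 in the same exact test. By depth the pooled P-CM shares in 1N and 2N nuclei were 3.12% and 3.41% under 1000 counts. They were 4.89% and 5.92% from 1000 to 1500 counts, and 9.46% and 10.02% from 1500 to 2500. Only from 2500 counts on were they far apart, at 10.4% and 17.6%. The share of CM3 nuclei was higher in 1N nuclei in 12 of 12 clones and that of CM1 lower in 11 of 12, each with an adjusted p of 0.00244 in that test, and that of CM2 had an adjusted p of 0.405. These shares are not independent of the gene changes, and their sizes are not given, because genes that lead the classes, such as SPHKAP, ERBB4 and ANKRD1, changed themselves.

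Batch codes n3 (2273 nuclei) and n4 (1040 nuclei) belong to different clones, and the labels do not say which harvest day each code had. Among 7 n3 and 11 n4 clones, edgeR called 41 genes higher and 6 lower in n3 of 8881 tested, with 404 at an unadjusted p under 0.05. The scrambled clone, coded n4, is the only tested clone of its hairpin. With the target as covariate it therefore adds nothing to this difference, though it counts among the n4 clones. The balance of directions depended on the method, with 87.2% of the called genes higher here, 67.2% with library size alone, which moved the median of all genes by -0.12 on the log2 scale, 66.7% with DESeq2 and 71.03% with no target covariate. The ventricular light chain gene MYL2 was higher by 2.81 ± 0.27 on the log2 scale (SE), with a mean over clones of 575 ± 338.3 CPM (SD, n = 7) against 113.2 ± 110.2 CPM (n = 11). The natriuretic peptide gene NPPA was higher by 1.99 ± 0.22, with means of 2394 and 791 CPM. The myosin heavy chain gene MYH7 was higher by 1.25 ± 0.17, with means of 12038 and 5399 CPM, and all 7 n3 clones lay above all n4 clones. CRYAB, RRAD, DES, ALDOC, TNNT1, HSPB2 and KRT19 completed the 10 by p, with log2 changes of 1.35 to 3.28. MCTP1 (-1.83), ENC1 (-1.92), RSPO3 (-1.78), CNTN5 (-1.08) and SLIT3 (-0.91) were lower in n3 clones. DESeq2 called 0.540% of the genes, with 26 of the 47 in common, and DES (1.57), MCTP1 (-1.55) and CNTN5 (-1.09) did not pass with it, while TNNT1, HSPB2 and ENC1 were given no adjusted p. The share of CM2 nuclei was higher in n3 clones, with an adjusted p of 0.0179 in an exact permutation test, and its size is not given because the CM2 genes MYL2, CRYAB, ALDOC and RRAD changed themselves. Within the CM2 class alone MYL2 (4.94), NPPA (2.75), MYH7 (2.16), CRYAB, RRAD, DES, ALDOC, KRT19 and CNTN5 (-2.12) passed again, and RSPO3 (-1.07), SLIT3 (-0.25) and MCTP1 (0.51) did not. ALDOC (1.23), KRT19 (0.92), CNTN5 (-0.56) and SLIT3 (-0.45) did not pass in 2N nuclei alone, nor RSPO3 (-1.004) and ENC1 (-1.44) in 1N nuclei alone, nor RSPO3 (-1.29) in clones with at least 20 nuclei. The number of calls depended on single clones, with 9 genes called without GATA4 clone GTCTAA (539 nuclei) and 22 without SMAD2 clone AGACTC (784 nuclei). Without NKX2-5 clone TCAACC (599 nuclei) 55 were called, and the reason for these differences was not tested.

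**Figure D2:**
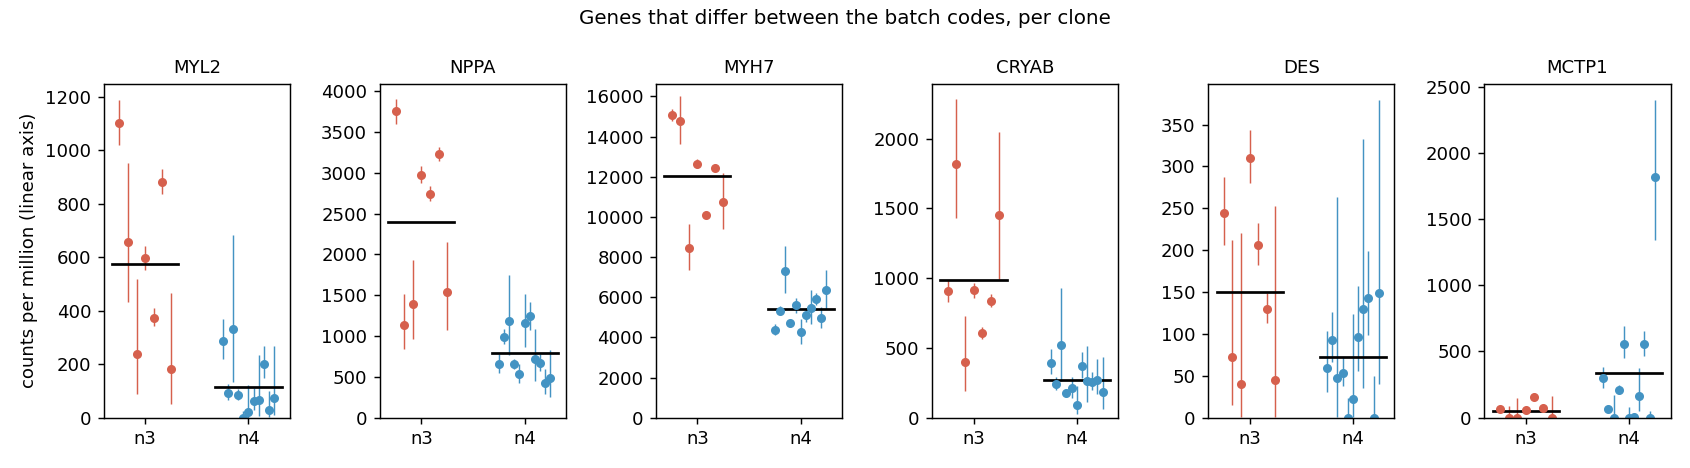
CPM per clone in n3 and n4 clones on linear axes, with a point per clone, 95% Poisson intervals and a black line at the mean over clones. MYL2 had a mean of 575 CPM in n3 and 113.2 CPM in n4 clones, and every n3 clone lay above every n4 clone for MYH7.

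Contractile genes were among those that differed between n3 and n4 clones. The sarcomere list rose, with 7 of 27 genes past the threshold including DES and CSRP3 (1.15), and kept its camera call with an estimated correlation at an adjusted p of 0.0214. The ventricular list did so at 0.00374, with MYL3 (0.82) and FHL2 (0.93) beside MYL2 and MYH7. The glycolysis and hypoxia list rose with 3 of 17 genes over all genes tested and 9 adjusted over the list alone, among them ALDOC and SLC2A1 (1.02), at an adjusted p of 0.0192 with an estimated correlation. The atrial list, through NPPA, had 0.0322 and the heat-shock list, through HSPB7 (0.80), had 0.0117 in the same camera test. The oxidative metabolism list, with FABP3 (1.07), had adjusted p = 0.244 with an estimated correlation and lost its call. HRC (1.04) of the calcium list and HOPX (1.81) of the cardiac transcription factors rose in lists that camera did not call. With DESeq2 FHL2 (0.81) and HRC (1.12) did not pass and HOPX was given no adjusted p. In 2N nuclei alone FHL2 (0.61), SLC2A1 (0.52), FABP3 (0.58) and HRC (1.09) did not pass, and in 1N nuclei alone HRC (0.99) and HOPX (0.60) did not. In the CM2 class HRC (0.78) and HOPX (1.704) did not pass, and with no filter FHL2 (0.98) did not. The chromatin, extracellular matrix, interferon, p53, proliferation, TGF-beta and WNT lists were not called. Pooled CPM differed 2-fold or more for 2.53% of 10452 genes, 57.6% of these higher in n3. LINGO1 led at a ratio of 8.50, and HAS2, at 0.19, was the lowest.

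Whether each hairpin lowered its own gene was tested on clone sums of nuclear counts. Cytoplasmic RNA was not measured, so a loss of RNA there could not be seen. In simulated counts the fit against the scrambled clone called 0% to 5% of 2-fold changes, so a loss of that size could be missed. No targeted gene differed from the scrambled clone by edgeR, with p from 0.1999 to 0.972 unadjusted and from 0.970 to 0.972 adjusted over the 5 targeted genes alone. The fold in hairpin clones over the scrambled clone was 0.915 for GATA4 (95% interval 0.514 to 1.63), 0.874 for NKX2-5 (0.417 to 1.83), 0.897 for SMAD2 (0.423 to 1.90), 2.54 for KMT2D (0.610 to 10.6) and 1.02 for CHD7 (0.354 to 2.93). GATA4 had 724 ± 215.97 CPM (SD, n = 7) in its hairpin clones and 755 CPM in the scrambled clone. NKX2-5 had 208.3 ± 187.3 CPM (n = 3) against 310.2 CPM, and SMAD2 had 109.7 ± 56.3 CPM (n = 3) against 146.7 CPM. KMT2D, with 4 counts in the scrambled clone, had 45.3 ± 21.9 CPM (n = 3) against 16.8 CPM, and CHD7 had 112.6 ± 65.2 CPM (n = 2) against 79.7 CPM. Against all other clones the intervals were narrower, and the folds were 0.95 for GATA4 (0.734 to 1.23), 0.845 for NKX2-5 (0.548 to 1.30), 0.915 for SMAD2 (0.636 to 1.32), 0.914 for KMT2D (0.511 to 1.63) and 0.848 for CHD7 (0.435 to 1.66). By hairpin, pooled SMAD2 counts were 91.3 CPM with SMAD2.4 (77.2 to 107.3) and 172.9 CPM with SMAD2.2 (120.4 to 240.5), and 58.8 CPM with SMAD2.3 on 3 counts (12.1 to 171.96), against 157.2 CPM with the scrambled hairpin (112.3 to 214.04). Of the 785 nuclei with SMAD2.4, 784 were a single clone coded n3, while the scrambled clone is coded n4. Pooled NKX2-5 counts were 101.4 CPM with NKX2.5.3, on 9 counts over 5 clones (46.4 to 192.6), 260.5 CPM with NKX2.5.2 (233.6 to 289.7) and 326.2 CPM with the scrambled hairpin (259.8 to 404). A limit of 3 counts in NKX2-5 clone TATGAC is 111.3 CPM, 2.79-fold below the scrambled clone's value, whose own counting error is left out. That NKX2-5 clone had 0 of 26959 counts. In n4 clones alone it is the single NKX2-5 clone against the single scrambled clone, so both were assumed to vary like clones of other targets, and under that assumption the difference had p = 0.000265, adjusted to 0.00132 over the 5 targeted genes and to 0.346 over all genes, and without this clone the log2 difference over all clones was 0.38. Pooled GATA4 counts were 652 CPM with GATA4.1 (603 to 704) and 686 CPM with GATA4.3 (648 to 727) against 751 CPM with the scrambled hairpin (648 to 865). KMT2D and CHD7 hairpins each had at most 26 counts of their gene. These pooled intervals cover counting error and leave out the spread between clones.

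**Figure D3:**
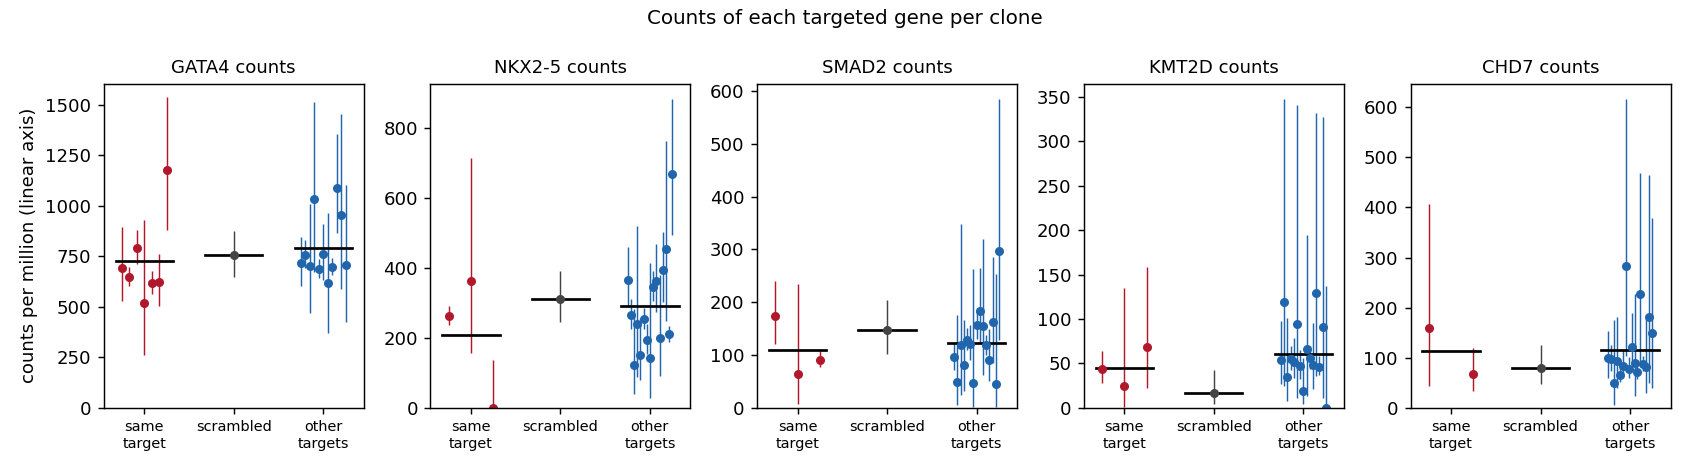
CPM of each targeted gene per clone on linear axes, for clones with a hairpin against it, the scrambled clone and clones of other targets, with 95% Poisson intervals and a black line at the mean over clones. GATA4 had a mean of 724 CPM in its 7 hairpin clones and 755 CPM in the scrambled clone.

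Genes elsewhere in the genome were then compared between each target and the scrambled clone, over 8881 genes. CHD7 clones had 3 lower genes by edgeR and 3.45% of all genes at an unadjusted p under 0.05, while DESeq2 called 0. These were MCTP1 (-6.50 ± 0.99, adjusted p 5.39e-07), COL1A1 (-3.03 ± 0.60) and COL3A1 (-3.26 ± 0.69), and 0 were called without clone CTCGCT. MCTP1 had 553 CPM (463 to 656) in the scrambled clone and 1 count in CTCGCT, 6.05 CPM with an interval of 0.153 to 33.7. The smaller CHD7 clone had 0 of 25209 counts, which allows up to 119.01 CPM of MCTP1. In all clones other than CHD7 together MCTP1 was at 140.8 CPM (132.1 to 150.04), in single clones at 0 to 1818 CPM, and it was not among the genes called for CHD7 against all other clones. This spread of MCTP1 between clones did not enter its SE or p against the scrambled clone. GATA4, NKX2-5, SMAD2 and KMT2D clones had 0 genes past the threshold by edgeR and by DESeq2, with 2.52%, 2.13%, 2.35% and 2.43% of genes at an unadjusted edgeR p under 0.05, where chance gives 5%. Single clones moved some of these counts. SMAD2 had 6 genes without clone AGACTC and 4 without TCTATT, KMT2D had 1 without CGCGAG, NKX2-5 had 1 without TATGAC, and CHD7 had 4 without GTGGGG.

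Against all other clones, edgeR called 6 genes for CHD7, 2 for KMT2D and 1 for GATA4. In CHD7 clones the potassium channel subunit KCNIP2 (3.33 ± 0.64), EPHX3 (4.43 ± 1.01) and SBNO2 (2.54 ± 0.58) were higher and the collagen genes COL1A1 (-3.08 ± 0.57), COL3A1 (-3.74 ± 0.70) and COL1A2 (-3.00 ± 0.66) lower. KCNIP2 had 10 and 12 counts in the CHD7 clones. Of the CHD7 clones, 0 genes were called without GTGGGG and 4 without CTCGCT. In KMT2D clones PLAT, the gene of tissue plasminogen activator, was lower (-5.45 ± 0.93, adjusted p 0.000438), as was the sulfatase gene SULF1 (-3.13 ± 0.67, adjusted p 0.0365). PLAT had 1 count in the 3 KMT2D clones together, and 0 genes were called without KMT2D clone CGCGAG and 1 without either of the others. Outside the CF class 0 genes were called for KMT2D. PLAT was at 6.72 CPM (4.78 to 9.18) and SULF1 at 1.21 CPM (0.485 to 2.48) in those nuclei of other clones, against 896 and 1020 CPM in their CF nuclei. With so few counts outside the CF class, the lost calls do not show that levels were equal there. CF nuclei were 2.73% of the nuclei in KMT2D clones and 5.38% in other clones. PLAT did not pass in 1N nuclei alone, nor SULF1 in either code alone, with library size alone, with no batch covariate or in clones with at least 20 nuclei. In GATA4 clones CNTN5 was higher (1.12 ± 0.23, adjusted p 0.0302), a call that ended without any of the clones TTAGTA, CCTCAT or GACATT, and in 2N nuclei alone. NKX2-5 and SMAD2 clones had 0 calls by edgeR, with 1.10% and 1.44% of genes at an unadjusted p under 0.05, although SMAD2 had 10 without clone AGACTC and 3 without TCTATT. With DESeq2, KCNIP2, EPHX3 and SBNO2 also passed, and the collagen genes, PLAT, SULF1 and CNTN5 did not. All 3 collagen genes had smaller log2 differences outside the CF class, from -1.19 for COL1A1 to -1.83 for COL1A2, and none passed there, nor in either code alone. SBNO2 (2.38) did not pass outside the CF class either, and EPHX3 was removed by the filter there and in 2N nuclei alone. KCNIP2 did not pass in 2N nuclei alone, and in 1N nuclei alone the filter removed KCNIP2, EPHX3 and SBNO2 and 0 genes were called for CHD7. EPHX3, SBNO2 and COL1A2 did not pass with no batch covariate, COL1A2 with library size alone, and EPHX3 and SBNO2 (adjusted p 0.0517 and 0.0520) without GATA4 clone CTTCGG, which is labelled with both batches. In clones with at least 20 nuclei 0 genes were called for CHD7.

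Camera called 9 of 75 combinations of list and target against the scrambled clone, and 0 held with an estimated correlation or by fry. All 5 targets share that single control clone, so their directions are not independent. The sarcomere list was lower for NKX2-5 (adjusted p = 0.833 with an estimated correlation), SMAD2 (0.962) and CHD7 (0.962). The ventricular list was lower for GATA4 (adjusted p = 0.727 with an estimated correlation), NKX2-5 (0.727) and CHD7 (0.653). The proliferation list was lower for GATA4 (adjusted p = 0.653 with an estimated correlation) and KMT2D (0.653), with MKI67 at -1.58 and RRM2 at -1.80 for GATA4. The extracellular matrix list was higher for SMAD2 (adjusted p = 0.833 with an estimated correlation), where 8 of 24 genes rose adjusted over the list alone. Without the CF class it was not called, and its direction was down (adjusted p = 0.990 with an estimated correlation). CF nuclei averaged 5.43% of the nuclei over SMAD2 clones, 7.69% at most, and were 2.63% of the scrambled clone, while the list summed to 46412 CPM in CF nuclei against 3653 to 4895 CPM in the cardiomyocyte classes.

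Class shares per clone did not differ from the scrambled clone in any of 25 exact permutation tests, which could not reach p under 0.125 for GATA4, 0.25 for the targets with 3 clones or 0.333 for CHD7. Against all other clones the lowest adjusted p was 0.233, for P-CM nuclei in GATA4 clones, which were 5.11 ± 3.02% (SD, n = 7) against 11.3 ± 5.05% (n = 12), with p = 0.00933 before adjustment in an exact permutation test.

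Spread between clones, as the common biological coefficient of variation, was 0.261 over all 19 clones on 8881 genes and 0.228 over the 18 targeted clones on 5281 genes, so these values differ in the genes they rest on. In clones with at least 20 nuclei it was 0.188 over all 13 clones on 8602 genes and 0.192 over the 12 targeted clones on 9523 genes. The scrambled arm had a single clone in the tests, so its spread could not be measured.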

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

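Tests chosen only after the result was seen were the CF-class and CM2-class tests of the n3 and n4 clones and the CF-class test of the CHD7 clones, and all edgeR tests between the condition or batch codes are unplanned additions.

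Among 27 sets of values over the 7 GATA4 clones or the 7 n3 clones, 4 held a clone far from the others. A chance count of 1.35 would need independent sets and clones of like size. Neither holds, since the sets share clones and small clones have more counting error. GATA4 clone GAGTGG had 1177 CPM of GATA4, while the other 6 clones with GATA4 hairpins had 519 to 791 CPM. GATA4 clone CTTCGG had 18.8% CF nuclei (6 of its 32 nuclei), while the others had 0 to 6.79%. CHD7 clone GTGGGG had 912 CPM of CNTN5 among n3 clones that otherwise had 121.3 to 431 CPM, and 158.7 CPM of SLIT3 where the others had 728 to 997 CPM. That clone had 11 nuclei and 25209 counts.

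The difference between condition codes was not the same in the batch codes for 32 of 3730 genes in an edgeR interaction test over 4 n3 and 7 n4 clones, with 420 at an unadjusted p under 0.05. Of the genes that the naming rule takes for the condition codes or their lists, 7 were among them. CCN2 fell by 1.99 on the log2 scale in n3 clones and by 0.35 in n4 clones, an interaction of -1.68 (adjusted p 3.48e-05). VCAN changed by -0.11 and 1.33 (interaction -1.40, adjusted p 0.000143), and the WNT receptor gene ROR1 by 0.02 and 1.06 (interaction -1.02, adjusted p 0.0126). KRT18 changed by -0.75 in n3 and -1.68 in n4 clones (interaction 0.91, adjusted p 0.0263), and KRT8 by -0.54 and -1.21 (interaction 0.66, adjusted p 0.0439). The glycolysis genes ALDOA, with 0.13 and -0.46, and SLC2A3, with -0.38 and -1.38, had interactions of 0.58 and 0.98 (adjusted p 0.0437 for each). Genes named for other comparisons were among them too, MYL3 with 0.10 in n3 and -0.56 in n4 clones, KRT19 with 0.38 and -0.83, ADAMTS19 with 2.04 and 0.10, and CNTN5 with -0.45 and 0.96.

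Higher counts of long genes such as ERBB4, TTN and CACNA1C in 1N nuclei may come from a larger share of unspliced nuclear RNA, and Spearman's rho between change and span was 0.529, 0.347 within n3 clones and 0.508 within n4 clones. With a span trend removed, 34.2% of the 632 called genes still passed, a value between the bounds set beforehand, so whether the trend is the whole cause stays open. That fit called 7.59% of the 3730 genes instead of 16.9%, and the 632 genes kept 0.77 of their log2 change (95% interval 0.74 to 0.79). Depth alone is argued against, since nuclei of like depth kept 0.94 of the change (0.91 to 0.97), and 1 of 100 swaps of the codes within clones, the real one, gave as many genes, the highest other giving 91. With clone and class together as the block the slope was 0.63 (0.60 to 0.66), and the shares of CM1 and CM3 differed between the codes (adjusted p 0.00244 for each in an exact sign-flip test), but the classes were set from the same counts, so a different mix of classes cannot be told apart from the codes, and the labels name no biological difference between 1N and 2N to test.

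Higher MYL2, MYH7 and NPPA in n3 clones, with 41 risen and 6 fallen genes (66.7% risen with DESeq2 and 67.2% with library size alone), could reflect the harvest day, the preparation or the clones that each code holds. The tables argue against a few technical sources, since 100% of the 47 called genes passed again without the CF class, the risen genes had a slope of 1.39 (1.22 to 1.55) in CM2 nuclei alone although the share of CM2 nuclei differed, the smaller slope within a condition code was 0.99 (0.87 to 1.10), and the lowest median size with an n3 clone left out was 1.11 against 1.25. Over all genes Spearman's rho with span was -0.039, which argues against a general length trend, yet the risen genes had a median span of 11.6 kb and the fallen ones 485 kb, so an effect of length on these genes is not excluded. Of 100 splits of the clones 1, the real one, gave as many genes, and the highest other gave 25. For the fallen genes the slope in CM2 nuclei was 0.41 (-0.12 to 1.13), so a different mix of classes cannot be told apart there with so few genes, and harvest day and preparation cannot be separated from the code and were not tested.

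Lower COL1A1, COL3A1 and COL1A2 counts in CHD7 clones may follow from fewer CF nuclei, since the larger CHD7 clone had 0 of 88 nuclei in that class, although the smaller had 1 of 11 (9.09%), and none of these calls against all other clones held with either clone left out. Without the CF class their mean log2 difference from all other clones was -1.59, against -3.27 with it. Free RNA from CF nuclei as the only source stays open, since 25.1% of the collagen counts of other clones lay in cardiomyocyte-class nuclei, above the bound of 10% set beforehand for that source, while COL1A1 in those classes was 86.3 CPM (49.3 to 140) in CHD7 clones and 247.6 CPM (235.5 to 260.2) in others, not equal as its alternative required. An effect of CHD7 on collagen genes was not separated from either, with 2 clones of which 1 had 11 nuclei.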

How the results depend on the processing

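Fits on a single condition or batch code or on the CM2 class, and the alternatives for the code comparisons, were chosen after the data were examined. Of the alternatives for the main results, 72.3% kept their sign and call status or, for counts and spreads, stayed near their value. Of the rest, 35 counts or spreads moved and 14 log2 differences changed sign. A log2 difference that kept its sign and call status could still change in size. No knockdown alternative of 64 passed the threshold over all genes by edgeR or DESeq2, and 43 were below zero. Adjusted over the 5 targeted genes 1 passed, NKX2-5 in n4 clones with a fitted -8.95 (adjusted p 0.00132), which rests on a clone with 0 counts and is no bound. The cause was not tested for any change below. The KMT2D and CHD7 knockdowns in clones with at least 5 nuclei have no value, because neither gene passed the filter there, and no clustering was run, since the authors' classes were used.

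Among the main results, sign changes were all in the knockdown. NKX2-5 became 0.042 with library size alone, where the median of all genes moved by 0.177, 0.37 in clones with at least 20 nuclei and 0.66 in 1N nuclei, with leave-one-out values from -1.02 to 0.38. SMAD2 became 0.48 in 2N nuclei, and KMT2D -0.13 against all other clones. CHD7 became -0.012 with no filter, -0.25 in clones with at least 20 nuclei, -0.24 against all other clones, -0.41 without the CF class, -0.026 with no batch covariate, -1.19 in 2N nuclei and -0.28 in n4 clones, and leaving out a CHD7 clone gave -0.25 to 0.95.

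Counts of genes per target also moved. GATA4 had 1 gene with no filter, 1 against all other clones and 2 in 2N nuclei. NKX2-5 had 1 in 1N and 1 in 2N nuclei, and 0 to 1 with a clone left out. SMAD2 had 3 with library size alone, 2 without the CF class, 7 in n4 clones, and 0 to 6 with a clone left out. KMT2D had 2 against all other clones, 1 with no batch covariate, 1 in 1N nuclei, 1 in n4 clones, and 0 to 1 with a clone left out. CHD7 had 0 with DESeq2 (3.12% of genes at an unadjusted p under 0.05), 0 in clones with at least 5 nuclei, 6 against all other clones, 1 without the CF class, 1 with no batch covariate, and 0 to 4 with a clone left out. Camera's 9 list calls became 0 with an estimated correlation, 0 by fry, 5 without the CF class and 0 against all other clones with an estimated correlation.

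For n3 against n4 the share of tested genes called, 0.529% of 8881, became 1.07% in clones with at least 20 nuclei, 1.20% with no target covariate and 0.122% to 0.746% with an n3 clone left out. In the CM2 class it was 1.69% of 4434 genes, and MCTP1 changed sign to 0.513. For 1N against 2N the share of 16.9% became 3.50% in the CM2 class, where fewer clones and nuclei remained and KRT8 changed sign to 0.0502, ANKRD1 to 0.419, TAGLN to 0.538 and TRDN to -0.0530, and 12.9% in n3 clones, where VCAN changed sign to -0.111, and 8.70% in n4 clones. The common coefficient of variation of targeted clones, 0.228, became 0.192 in those with at least 20 nuclei, on 9523 genes instead of 5281. The CPM ratio of FN1 between n3 and n4 fell from 1.25 to 0.806 without the CF class. Of the alternatives for CPM ratios, 93.9% stayed within counting error of their value, 21 moved and that of FN1 alone reversed. Class shares passed in none of their alternatives by the exact permutation test, which cannot reach 0.05 against the single scrambled clone. Against all other clones the lowest adjusted p was 0.194, in 2N nuclei. Depth limits the CHD7 and KMT2D genes most, with KMT2D at 4 counts in the scrambled clone.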

Other observations

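The tests of single clones and the values in CF nuclei of KMT2D clones were chosen after the data were examined.

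Each of the 10 clones with at least 50 nuclei was compared with all other clones by edgeR, with a single clone in that arm, which was assumed to vary like the others. No gene passed for GATA4 clone GTCTAA, NKX2-5 clone TCAACC, CHD7 clone CTCGCT or SMAD2 clone AGACTC, with 0.507%, 0.664%, 4.79% and 0.327% of genes at an unadjusted p under 0.05. In the other 6 clones, SMAD2 clone TCTATT had higher EFEMP1 (5.54), CNTNAP2 (2.64), SERPINE2 (3.25) and NLRC3 (2.26) on the log2 scale. GATA4 clone CCTCAT had higher SST (4.27), the somatostatin gene, and ACTG2 (3.49). GATA4 clone TTAGTA had higher GDF15 (3.50) and BAP1 (1.80). GATA4 clone GACATT had higher ATP13A2 (2.31), CNTN5 (1.92) and TMEFF2 (5.90). The scrambled clone had higher PENK (4.38), the proenkephalin gene, and KMT2D clone CGCGAG had lower PLAT (-5.22).

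In the 9 CF nuclei of KMT2D clones, PLAT had 0 of 19013 counts, which allows up to 157.8 CPM, while CF nuclei of other clones had 896 CPM (813 to 984). SULF1 was at 368.2 CPM (148.02 to 759) against 1020 CPM (932 to 1115), and COL1A1 was at 8678 CPM against 8360 CPM in the same nuclei. These genes were chosen after their values were seen.

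Splits of the clones into groups of the same sizes show how often chance gives as many genes against all other clones. For KMT2D, with PLAT and SULF1 called, 24 of 100 splits gave at least 2 genes, and the highest other gave 16. For GATA4, with CNTN5 called, 41 of 100 splits gave at least 1 gene, and the highest other gave 17. Chance cannot be excluded for these counts. NKX2-5 and SMAD2 had 0 genes, so all 100 splits give as many by design and say nothing of chance there, with highest others of 11 and 12. The median of the other splits was 0 genes for each of these targets. Why a few splits gave many more genes was not tested. No such splits were drawn for CHD7, so chance was not tested this way for its calls.

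A hypothesis is that each clone has an expression profile of its own that its nuclei share in both condition codes. Profiles were deviations from the mean of a clone's batch code. Over 2432 genes in 10 clones, the 1N profile lay nearest to the same clone's own 2N profile for 6 clones, where shuffled clone names gave 3 at their 95th percentile (permutation p 0.0007). Correlations across genes were low, with a mean r of 0.07 for the same clone and -0.01 for different ones, and genes are not independent replicates. Target and clone are not separated by this test.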
